A study of Rattus norvegicus with 9 samples.

How the data were processed

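The study measured genomic DNA of purified Sertoli cells in 9 libraries, 3 each from the control, DDT and vinclozolin lineages, as methylation profiling by sequencing. The labels end before the library steps, so the enrichment step is not named and a count is read here only as a number of sequenced reads. The labels do not say whether the 3 libraries of a lineage came from separate animals. P-values of comparisons between libraries therefore measure no spread beyond these libraries. Pairs of libraries of a lineage differed by a mean chi-square of 2.63 to 3.52 per 1 kb bin, where counting noise alone gives 1.

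The deposited tables held 27820300 windows of 100 bp of the rat genome build Rnor_6.0. Per the file headers, the values per library were raw read counts, whole numbers from 0 to 300, and 300 was the maximum in each of the 9 libraries. The authors deposited an edgeR log2 fold change for each window, which was positive where the control libraries were higher. The authors also deposited an unadjusted p-value for each window, left empty where the 6 libraries compared summed to under 40 counts. Per the labels, the submitters used FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR, without versions or settings. The deposited RPKM values were not used. The control counts appeared in both tables with the same values and were read once.

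Counts of 10 neighbouring windows were summed to 2782023 bins of 1 kb. The 1604749 bins (57.7%) on chromosomes 1 to 20, X and Y with a mean of at least 20 counts over the 9 libraries were tested. Their median mean count was 45.8. Library totals ran from 77948275 to 157198696 counts, and TMM factors from 0.98 to 1.02. A single edgeR model with 1 term per lineage was fitted to all 9 libraries, which left 6 residual degrees of freedom (edgeR 4.0.16, quasi-likelihood F test, R 4.3.3, limma 3.58.1, DESeq2 1.42.0, data.table version 1.17.8, matplotlib 3.10.9). The dispersion was 0.01 and the prior degrees of freedom 74.8. Against 6 residual degrees of freedom, the variance used for a bin therefore came mostly from all bins together. A bin could be called although its own libraries differed widely. Bins with a Benjamini-Hochberg adjusted p under 0.05 were called in each of the 3 comparisons, and called bins of the same direction within 1 kb of each other were merged to regions. Each log2 fold change is the first named lineage minus the second. CPM are counts scaled to the TMM-adjusted total of a library over the tested bins, given as mean ± SD with n = 3.

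The test was checked on simulated data. With 67, 67 and 66 bins changed by 1.5, 2 and 4-fold, the DDT comparison recovered 0%, 13.4% and 81.8% of them and the vinclozolin comparison 0%, 0% and 75.8%, with 0 and 2 unchanged bins called. In 5 simulations without change, in which both exposed groups were set against the same simulated controls, edgeR called 0 bins in either comparison. All 9 libraries were simulated, and each bin was drawn on its own. Differences between libraries that run across bins were therefore left out, and the 0 calls do not cover them. None of the simulated differences of 1.5-fold was recovered. The adjusted p depends on how many bins change, and the simulation changed far fewer than the 1236 bins called for DDT in the data. These shares are therefore no detection limit for the data, where the smallest absolute log2 fold change called for DDT was 0.73.

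The bins, test, threshold, comparisons and most alternatives were fixed before the data were examined. So was the rule for naming bins, which rested on annotated genes. The reference in hand was of another genome build than the deposited coordinates, so the rule was applied without genes. For each comparison and direction it took the 10 called bins with the smallest p in which the libraries of both lineages did not overlap, at most 1 per 10 kb. Promoter counts, gene lists, cell type marker lists, annotation classes and sequence composition were for the same reason not analysed here, and positions stand without genes.

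The chromosome distribution of called bins was tested with Fisher's exact test, two-sided, against all tested bins, in 88 tests of 22 chromosomes, 2 directions and the 2 comparisons with control. Those tests treat bins as independent units and hold no spread between libraries, and the same is true of their intervals. Shares of counts per library were compared by exact permutation tests, two-sided, which with 3 against 3 libraries cannot go below p = 0.1, in a family of 21. The alternatives fixed in advance were other normalizations (DESeq2 size factors, total counts, a loess offset with span 0.3), count minimums, bin sizes, an adjusted p under 0.1, an earlier quasi-likelihood fit, limma-voom, fits of the 6 libraries compared, the replicate number as a block, and each library left out. Chosen after seeing the data were the offset from the surrounding 100 kb, the share of counts on chromosome 12 or the log2 total count as covariate, counts thinned to the smallest library, bins with every window at 150 or less, the chromosome tests under both offsets, and the share on X without the top 1% of bins. All 10 splits of the 6 libraries of each comparison were also fitted.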

Results

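DNA of Sertoli cells, the somatic cells that nurse germ cells in the seminiferous tubule, was sequenced in 9 libraries from rats of 3 lineages, with 3 libraries per lineage. The F0 dams had received DDT, an organochlorine insecticide, at 25 mg/kg per day, vinclozolin, a fungicide whose metabolites block the androgen receptor, at 100 mg/kg per day, or the vehicle alone on gestation days 8 to 14. Their F3 descendants were untreated, and cells were taken at 20 days of age. The control libraries held 119587815, 101142714 and 113126163 counts, the DDT libraries 103553153, 144555123 and 77948275, and the vinclozolin libraries 157198696, 92034517 and 82297795. Log counts per bin correlated at 0.83 to 0.88 between libraries of a lineage and at 0.80 to 0.89 between lineages, across bins, which are not independent replicates.

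The comparison of the DDT with the control lineage asked which genomic regions differed in F3 Sertoli cells. Among the regions far below control was a stretch of 3 bins on chromosome X from 73399001 to 73402000, with a mean log2 fold change of −2.77. Its last bin, 73401001 to 73402000, held 12.23 ± 1.29 CPM in control and 1.43 ± 0.42 CPM in DDT (SD, n = 3), an 8.83-fold lower level (log2 −3.14, SE 0.29, edgeR adjusted p = 1.58e-11). Bins with the same direction and a similar size started at 23599001 on chromosome 4 (log2 −2.91), 168667001 on chromosome 5 (log2 −2.61), 243283001 and 155529001 on chromosome 1 (log2 −2.68 and −2.26), 13948001 on chromosome 17 (log2 −2.66), 42966001 on chromosome 13 (log2 −2.46), 10324001 on chromosome 12 (log2 −2.61), 24137001 on chromosome 6 (log2 −2.39) and 130234001 on chromosome 8 (log2 −2.96). On chromosome 17 the level was 6.02 ± 0.64 CPM in control and 0.97 ± 0.18 CPM in DDT (SD, n = 3). Of these 10 bins, all but those from 155529001 on chromosome 1 and 130234001 on chromosome 8 held a window over 150 counts. Among all tested bins, 2325 of 1604749 did. In each of these 10 bins vinclozolin 2 was the highest vinclozolin library. In the chromosome X bin it held 11.79 CPM, against 1.85 CPM in vinclozolin 1 and 2.01 CPM in vinclozolin 3.

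**Figure D1:**
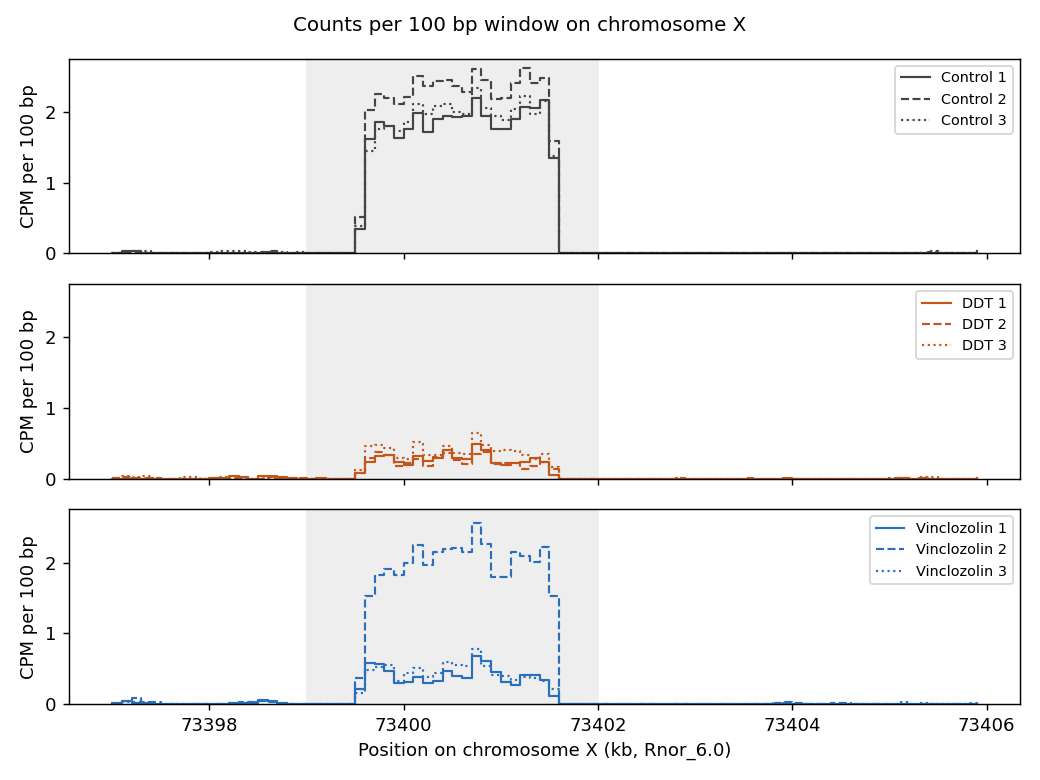
Read counts scaled to library size (vertical axis, CPM) in each 100 bp window along chromosome X (horizontal axis, kb, Rnor_6.0), with 1 line per library and the 3 bins from 73399001 to 73402000 shaded. The 3 DDT libraries, vinclozolin 1 and vinclozolin 3 lie below the 3 control libraries and vinclozolin 2 in the windows that start from 73399501 to 73401501. The windows on both edges of the shaded stretch are at or near 0 in all 9 libraries.

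Of the bins higher in DDT, the smallest p was at 49554001 to 49555000 on chromosome 3, where the DDT libraries held 64, 93 and 28 counts and the control libraries 4, 0 and 0 (log2 5.40, SE 0.63, edgeR adjusted p = 2.53e-08). This fold change rests on very few control counts. A stretch of 4 bins on chromosome 8 from 52243001 to 52247000 had a mean log2 fold change of 1.35. Its bin from 52244001 rose from 0.72 ± 0.18 CPM in control to 2.28 ± 0.21 CPM in DDT (SD, n = 3). Further bins higher in DDT started at 238522001 on chromosome 2 (log2 3.39), 150831001 on chromosome 4 (log2 1.87), 14433001 on chromosome 20 (log2 3.11), 7651001 on chromosome 15 (log2 2.44), 77270001 and 56522001 on chromosome 18 (log2 1.64 and 1.59) and 72175001 on chromosome 3 (log2 1.54). The bin from 34224001 on chromosome 19 rose from 2.73 ± 0.49 CPM to 5.28 ± 0.14 CPM (SD, n = 3, log2 0.96), and vinclozolin stood at 2.59 ± 0.30 CPM there. With the share of counts on chromosome 12 as a covariate, 15 of the 20 named bins of this comparison kept their call. Those lost included chromosome 8 from 52244001 (log2 1.15, edgeR adjusted p = 0.0811) and chromosome 15 from 7651001 (log2 1.75, edgeR adjusted p = 0.346). The other bins lost kept about the same fold change. They had log2 1.57 and 1.60 from 77270001 and 56522001 on chromosome 18 and 1.47 from 72175001 on chromosome 3 (edgeR adjusted p = 0.107, 0.0521 and 0.0805). The bin on chromosome 20 missed the threshold with limma-voom (log2 3.21, adjusted p = 0.0971), and the bin from 72175001 on chromosome 3 missed it without control 1 (log2 1.22, edgeR adjusted p = 0.0654).

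In all, 1236 of 1604749 tested bins were called by edgeR in DDT against control, 526 higher and 710 lower, with median log2 fold changes of 1.32 and −1.19. They formed 1180 regions, of which 1148 were a single bin. A change of over 4-fold was found in 131 bins, 93 of them lower in DDT. The libraries of both lineages did not overlap in 1234 of the 1236 bins, against 15.5% of all tested bins and 10% by chance. The called bins were selected on these same libraries, which largely brings this about, so it is no separate support. Without 1 library the count was 629 without control 1, 310 without control 2, 571 without control 3, 217 without DDT 1, 230 without DDT 2 and 938 without DDT 3. It was 2894 without vinclozolin 1, 1238 without vinclozolin 2 and 1058 without vinclozolin 3. With all 9 libraries it ran from 85 in bins of 10 kb to 60672 in windows of 100 bp, which had a count minimum of 10 in place of 20. The balance of directions was not stable, since 37645 of those 60672 windows, 2194 of 4364 bins at an adjusted p under 0.1 and 525 of 827 bins with the share of counts on chromosome 12 as a covariate were higher in DDT. Only 132 of the 1236 bins were still called with that covariate. All DDT libraries lay above all control libraries in that share, so the covariate overlaps with lineage. A call lost with it need not mean a smaller fold change.

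**Figure D2:**
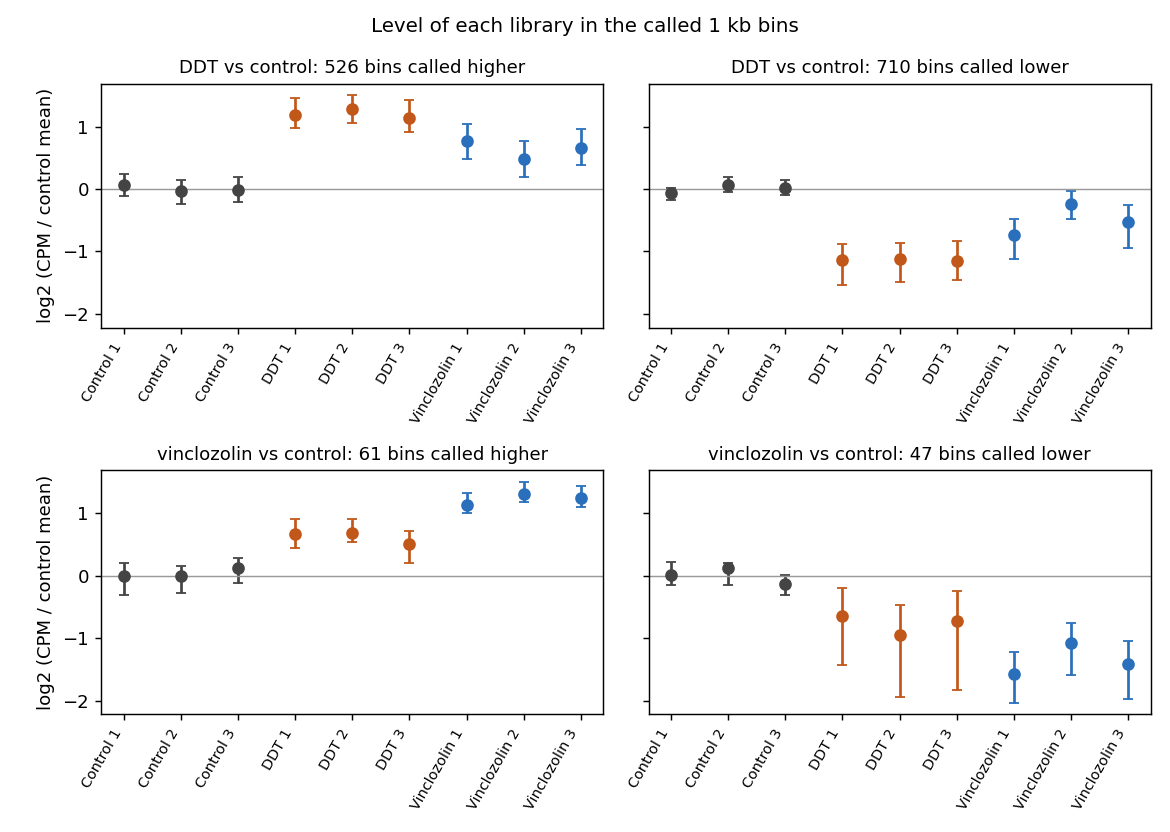
Level of each library in the called bins as log2 of CPM over the mean of the control libraries (vertical axis), with points for the median over bins and bars from the lower to the upper quartile. In the 710 bins lower in DDT the medians were −0.73 in vinclozolin 1, −0.24 in vinclozolin 2 and −0.52 in vinclozolin 3.

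The comparison of the vinclozolin with the control lineage asked the same question for the other exposure. The smallest p was at 23694001 to 23695000 on chromosome 3, which held 168, 201 and 139 counts in the control libraries, 186, 177 and 145 in DDT and 6, 8 and 1 in vinclozolin. The level fell from 1.71 ± 0.46 CPM to 0.05 ± 0.04 CPM (SD, n = 3, log2 −5.06, SE 0.36, edgeR adjusted p = 1.96e-17). The bin from 173488001 on chromosome 4 was 9.65-fold lower in vinclozolin (log2 −3.27, SE 0.34) and also lower in DDT (log2 −1.71, edgeR adjusted p = 0.000351). The bin from 115810001 on chromosome 2 was lower in both lineages, with log2 −3.86 in vinclozolin and −4.45 in DDT, as was that from 77176001 on chromosome 1, with 1.65 ± 0.03 CPM in control, 0.64 ± 0.11 CPM in vinclozolin and 0.64 ± 0.11 CPM in DDT (SD, n = 3). The bin from 168952001 on chromosome 3 was lower in vinclozolin (log2 −2.57, SE 0.31), and so was that from 173210001 on chromosome 4 (log2 −4.12, SE 0.62). The latter was also called lower in DDT (log2 −2.01, edgeR adjusted p = 0.0427). It rests on few counts, with 2, 0 and 6 in vinclozolin and 31, 3 and 1 in DDT. The bin from 150614001 on chromosome X had a log2 of −2.18, but control 1 held 1.76 CPM there against 0.45 and 0.42 CPM in the other control libraries, and without control 1 it was not called (log2 −1.14, edgeR adjusted p = 0.461).

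**Figure D3:**
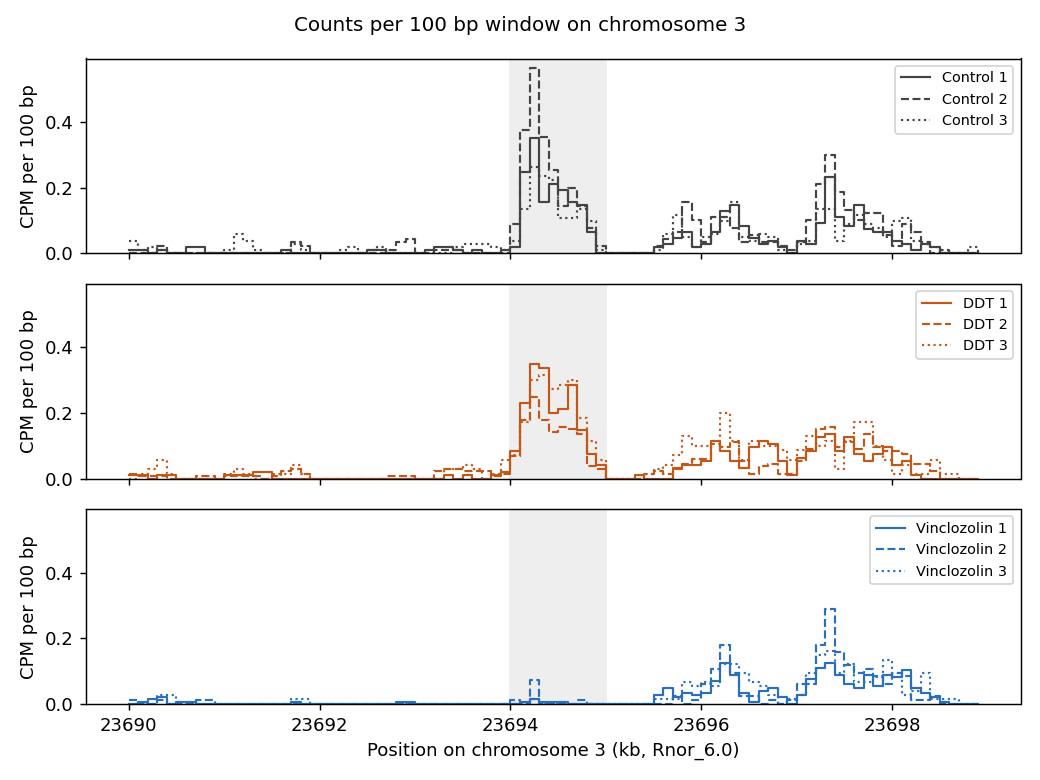
Read counts scaled to library size (vertical axis, CPM) in each 100 bp window along chromosome 3 (horizontal axis, kb, Rnor_6.0), with 1 line per library and the bin from 23694001 to 23695000 shaded. The 3 vinclozolin libraries held 6, 8 and 1 counts in the shaded bin.

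Among the bins higher in vinclozolin than in control, that from 9428001 to 9429000 on chromosome 20 rose from 0.38 ± 0.18 CPM to 1.17 ± 0.28 CPM (SD, n = 3, log2 1.58, SE 0.26, edgeR adjusted p = 0.00686) and was not called without control 1 (log2 1.25, edgeR adjusted p = 0.163) or without vinclozolin 3 (log2 1.48, edgeR adjusted p = 0.0819). The bin from 30841001 on chromosome 9 was higher in vinclozolin (log2 1.09) and in DDT (log2 0.96) and was not called for vinclozolin without control 2 (log2 0.96, edgeR adjusted p = 0.197). Of the 20 named bins of this comparison, 10 kept their call without control 1, 9 without control 2, 19 without vinclozolin 1, 17 without vinclozolin 2 and 10 without vinclozolin 3. Each of the 10 named bins higher in vinclozolin lost its call in at least 1 of these fits, which left 2 libraries in an arm. None turned its direction, which the selection of named bins without overlap between the libraries largely brings about.

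In all, 108 bins were called in vinclozolin against control by edgeR, 61 higher and 47 lower, with median log2 fold changes of 1.28 and −1.30, in 105 regions. The libraries of both lineages did not overlap in 103 of them, against 12.2% of all tested bins and 10% by chance. Here too the selection on the same libraries largely brings this about. Without 1 library the count was 32 without control 1, 18 without control 2, 235 without control 3, 53 without DDT 1, 165 without DDT 2 and 181 without DDT 3. It was 477 without vinclozolin 1, 158 without vinclozolin 2 and 14 without vinclozolin 3. With all 9 libraries it ran from 14 with at least 100 counts per bin to 1130 with the share of counts on chromosome 12 as a covariate. The lean to higher bins turned in several of these fits: 1 of 18 bins was higher without control 2, 41 of 158 without vinclozolin 2, 2 of 14 without vinclozolin 3, 10 of 57 with limma-voom, 12 of 37 in bins of 10 kb, 64 of 241 in windows of 100 bp, 15 of 36 with at least 1 count per bin, 8 of 22 with the earlier quasi-likelihood fit and 10 of 37 with the replicate number as a block.

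The bins called in a lineage were also read in the other. Of the 526 bins higher in DDT than in control, 98.5% were also above control in vinclozolin, and of the 710 lower bins 96.1% were also below it. The median log2 fold change of vinclozolin in these bins was 0.73 and −0.57. Of the bins called for vinclozolin, 98.4% of those higher and 87.2% of those lower had the same sign in DDT. The same 3 control libraries entered both comparisons and the selection of these bins, which alone gives shared signs without any change in the other lineage, and no value without change was computed for these shares. In 5 simulations of unchanged groups with shared simulated controls, the fold changes of all tested bins correlated at 0.49, against 0.56 observed (across bins, which are not independent replicates). The simulations left out differences between libraries that run across bins, so 0.49 does not cover these. Called in both lineages in the same direction were 26 bins, 7 higher and 19 lower, against 0.02 and 0.0208 for independent calls, and 0 were called in opposite directions, also at an unadjusted p under 1e-05. At an unadjusted p under 1e-05, 43 bins passed in both comparisons in the same direction. Those 5 simulations held no changed bins and edgeR called 0 bins in either comparison alone. Their overlap (1 bin under 1e-05 in 1 simulation and 0 in the others) therefore does not say how many shared bins the common controls add to real calls. That part was not measured, since groups of 3 cannot be divided with 2 libraries on each side. The shared count was 12 without control 1, 4 without control 2, 31 without control 3, 11 without DDT 1, 35 without DDT 2 and 47 without DDT 3. It was 13 without vinclozolin 1, 102 without vinclozolin 2 and 5 without vinclozolin 3. In part of the shared lower bins vinclozolin 2 stood near control. From 23599001 on chromosome 4 and 13948001 on chromosome 17 it held 2.87 and 5.14 CPM, against control means of 3.30 and 6.02 CPM. Both bins were called for vinclozolin (edgeR adjusted p = 0.0197 and 0.0118). The shared bin from 77176001 on chromosome 1 was low in all vinclozolin libraries, with 0.52, 0.65 and 0.74 CPM. A shared call is thus not by itself a change of the whole lineage.

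The direct comparison of the exposed lineages asked where the DDT and vinclozolin lineages differed from each other. The bin from 23694001 on chromosome 3 was higher in DDT (log2 5.10, SE 0.36, edgeR adjusted p = 1.15e-17), as were those from 7651001 on chromosome 15 (log2 5.10, SE 0.57) and from 49554001 on chromosome 3 (log2 4.30, SE 0.54). On chromosome X, a stretch of 5 bins from 150613001 to 150620000 had a mean log2 of 1.97. Its bin from 150618001 held 1.97 ± 0.42 CPM in DDT and 0.48 ± 0.06 CPM in vinclozolin (SD, n = 3). The control libraries differed among themselves there, with 2.56, 0.92 and 0.78 CPM. Control 1 likewise stood above the other control libraries from 77669001 on chromosome 5 (1.28 CPM against 0.02 and 0.15 CPM), from 50419001 on chromosome 19 (1.32 CPM against 0.44 and 0.32 CPM) and from 64933001 on chromosome 16 (2.83 CPM against 0.52 and 0.83 CPM). All 4 of these bins were called higher in DDT than in vinclozolin.

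Lower in DDT than in vinclozolin were clusters of neighbouring bins on chromosomes 1 and 14. A stretch of 6 bins on chromosome 1 from 11909001 to 11915000 had a mean log2 of −1.19, and in its bin from 11910001 the level was 3.20 ± 0.71 CPM in DDT, 9.79 ± 2.58 CPM in vinclozolin and 7.35 ± 2.44 CPM in control (SD, n = 3, log2 −1.58, SE 0.20). Stretches of 4 bins on chromosome 14 from 46635001 to 46640000 and from 46680001 to 46685000 had mean log2 values of −1.05 and −0.99. The bin from 46637001 held 3.11 ± 0.82 CPM in DDT and 7.33 ± 2.02 CPM in vinclozolin (SD, n = 3) and was not called without DDT 3 (log2 −1.02, edgeR adjusted p = 0.0531) or vinclozolin 2 (edgeR adjusted p = 0.141). Of the 20 named bins of this comparison, 12 kept their call without vinclozolin 2 and 18 without DDT 3.

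In all, edgeR called 417 bins between DDT and vinclozolin, 89 higher and 328 lower in DDT, in 371 regions. Without 1 library the count was 259 without control 1, 376 without control 2, 713 without control 3, 183 without DDT 1, 188 without DDT 2 and 50 without DDT 3. It was 4213 without vinclozolin 1, 21 without vinclozolin 2 and 133 without vinclozolin 3. Setting DDT 1, DDT 2 and vinclozolin 1 against DDT 3, vinclozolin 2 and vinclozolin 3, which does not follow lineage, called 1421 bins. With all 9 libraries and the lineages as groups, the count ran from 32 in bins of 10 kb to 3014 with the share of counts on chromosome 12 as a covariate. The lean to lower bins turned in windows of 100 bp, where 996 of 1631 were higher in DDT, and without vinclozolin 2, where 14 of 21 were.

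Called bins of DDT against control were spread unevenly over the chromosomes. Bins higher in DDT were over-represented on chromosome 12 (28 bins, odds ratio 2.32, 95% interval 1.53 to 3.40, adjusted p = 0.00187, Fisher's exact test), chromosome 10 (48 bins, odds ratio 2.06) and chromosome 20 (24 bins, odds ratio 1.98) and under-represented on chromosome 2 (23 bins, odds ratio 0.45) and X (3 bins, odds ratio 0.20). Bins lower in DDT were over-represented on X (48 bins, odds ratio 2.52, 95% interval 1.84 to 3.39, adjusted p = 3.2e-06, Fisher's exact test), chromosome 1 (106 bins, odds ratio 1.51) and chromosome 14 (54 bins, odds ratio 1.90) and under-represented on chromosome 10 (11 bins, odds ratio 0.32). For vinclozolin, bins lower than control were over-represented on chromosome 1 (12 bins, odds ratio 2.95) and chromosome 5 (9 bins, odds ratio 3.50). In all, 11 of 88 tests passed. With merged regions in place of bins 7 passed, and chromosome 14 (adjusted p = 0.342, Fisher's exact test), chromosome 20 (adjusted p = 0.0535, Fisher's exact test) and both vinclozolin results (adjusted p = 0.0535 and 0.06, Fisher's exact test) did not. For bins with an unadjusted p under 1e-05, chromosome 10 for higher bins did not pass (adjusted p = 0.708, Fisher's exact test), and chromosome 2, chromosome 20 and X for higher bins (adjusted p = 0.0913, 0.18 and 0.474, Fisher's exact test) and chromosome 1 for vinclozolin (adjusted p = 0.203, Fisher's exact test) did not pass either. The median log2 fold change of all tested bins in DDT against control was −0.12 on X, 0.08 on chromosome 10 and 0.10 on chromosome 12, and with an offset from the surrounding 100 kb 0 of the 9 DDT results were kept.

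**Figure D4:**
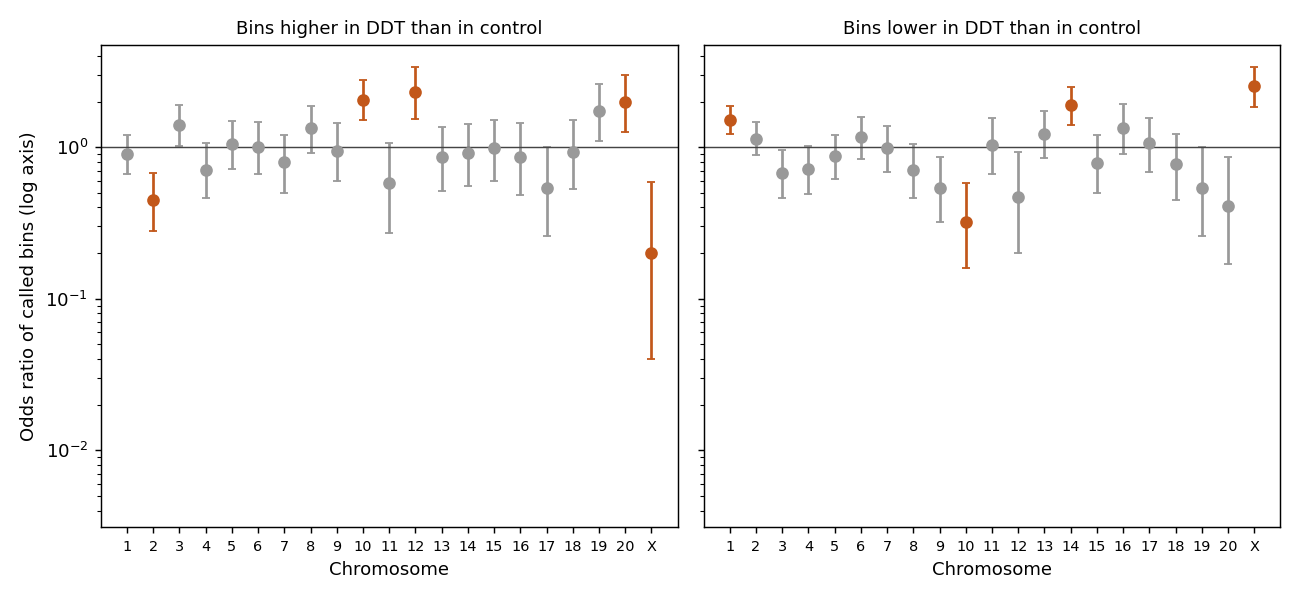
Odds ratio of called bins per chromosome (vertical axis, log scale) for bins higher (left) and lower (right) in DDT than in control, with 95% intervals as bars. Coloured points passed an adjusted p of 0.05, among them X with 0.20 for higher and 2.52 for lower bins.

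The share of counts on X was 3.04 ± 0.148% in DDT and 3.26 ± 0.112% in control (SD, n = 3), a difference of −0.218 that did not pass an exact permutation test (p = 0.2, adjusted p = 0.63 over 21 tests, smallest possible p = 0.1). It was 3.13 ± 0.134% in vinclozolin (exact permutation p = 0.3 against control). The share on chromosome 12 was 2.54 ± 0.0903% in DDT, 2.5 ± 0.0971% in vinclozolin and 2.38 ± 0.05% in control (SD, n = 3). Each exposed lineage lay wholly above control, at the smallest possible exact permutation p of 0.1 (adjusted p = 0.63). On chromosome 10 DDT lay wholly above control, with 4.53 ± 0.142% against 4.29 ± 0.0744% (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.63). The share of counts in the top 1% of bins was 8.52 ± 0.677% in DDT, 8.59 ± 0.945% in vinclozolin and 9 ± 0.495% in control (SD, n = 3), and the exact permutation p against control was 0.4 for DDT and 0.7 for vinclozolin.

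In the table the authors deposited, 14694 of 4860019 windows with a p-value had one under 1e-05 for DDT against control, 9947 of them higher and 4747 lower in DDT. For vinclozolin it was 664 of 4880098 windows, 310 higher and 354 lower. The balance moved with the threshold, to 52 higher and 93 lower under 1e-06 and 10 higher and 43 lower under 1e-07. For DDT it was 4033 higher and 2084 lower under 1e-06 and 1573 higher and 1067 lower under 1e-07. Of the 1236 bins called here for DDT 753 (60.9%) held a window under 1e-05, and of the 108 for vinclozolin 35 (32.4%) did. Under 1e-07 these shares were 32.8% and 9.3%. Of all 1604749 tested bins, 13090 held a window under 1e-05 for DDT and 598 for vinclozolin. Both tests used the same counts, so shared calls are not independent support. The DDT windows of the authors leaned to higher, while the bins called here leaned to lower, with 526 higher and 710 lower. These counts differ in unit and threshold, with 100 bp windows at an unadjusted p against 1 kb bins at an adjusted p. In the fit of 100 bp windows made here, 37645 of 60672 called windows were higher in DDT, the same lean as in the windows of the authors.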

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

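The splits of the samples, the thinned counts and both chromosome tests in this part were set out before their results were seen; the relation of depth with the concentration of counts and both tests of the bins far below control were chosen only after those results had been seen. The 3 patterns weighed, and the offsets and thinning that the tests use, were chosen after the values per library had been looked at, in place of others drafted before.

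In part of the called bins the 2 exposed lineages differed from each other by the edgeR test of that difference. This held for 18 of the 526 bins higher and 58 of the 710 bins lower in DDT than in control, and for 2 of the 61 bins higher and 16 of the 47 bins lower in vinclozolin than in control. Of all 1604749 tested bins, 417 differed. The called bins were selected on libraries that enter this difference again, which favours such calls, so the counts are no separate support. Among the named bins higher in DDT, the log2 difference of DDT minus vinclozolin was 4.30 from 49554001 on chromosome 3, 1.43 from 52244001 on chromosome 8, 1.84 from 238522001 on chromosome 2, 5.10 from 7651001 on chromosome 15, 1.24 from 77270001 on chromosome 18 and 1.01 from 34224001 on chromosome 19. The bin on chromosome 8 held 1.41 CPM in vinclozolin 1 against 0.42 and 0.43 CPM in the other vinclozolin libraries, and without vinclozolin 2 its difference was 1.17 (edgeR adjusted p = 0.138). Among the named bins lower in DDT it was −1.66 from 23599001 on chromosome 4, −1.89 from 73401001 on X, −1.46 from 168667001 on chromosome 5, −1.60 and −1.17 from 243283001 and 155529001 on chromosome 1, −1.37 from 13948001 on chromosome 17, −1.49 from 42966001 on chromosome 13, −1.50 from 10324001 on chromosome 12, −1.41 from 24137001 on chromosome 6 and −1.75 from 130234001 on chromosome 8. In each of these 10 bins vinclozolin 2 stood above the other vinclozolin libraries. Without vinclozolin 2 the bin from 42966001 on chromosome 13 had a difference of −0.71 (edgeR adjusted p = 0.642), and 21 of the 417 bins called between DDT and vinclozolin were left. That fit held only 2 vinclozolin libraries. Other named bins of the direct comparison that lost their call in it kept most of their difference. That from 30239001 on chromosome 16 went from −1.43 to −1.20. Since vinclozolin 2 stood apart in the 10 bins lower in DDT, their differences are not shown for the vinclozolin lineage as a whole. Among the bins named for vinclozolin it was −0.93 from 26289001 on chromosome 1, 5.10 and 2.18 from 23694001 and 168952001 on chromosome 3, 3.32 and 3.37 from 21674001 and 21698001 on chromosome 6 and 2.24 from 150614001 on X.

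Other splits of the same libraries were counted for each comparison. In DDT against control the lineages called 1236 bins and the highest other split 7, so that 1 of 10 splits gave as many. In vinclozolin against control the lineages called 108 and the highest other split 6, again 1 of 10. In DDT against vinclozolin 2 of 10 splits gave as many, with 417 bins for the lineages and 1421 for the highest other. In each case 10 splits are too few for a share under 0.05.

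The split with 1421 bins set DDT 1, DDT 2 and vinclozolin 1 against DDT 3, vinclozolin 2 and vinclozolin 3, the deeper against the shallower libraries, and points to a structure of the samples that crosses the lineages. With all counts thinned to the smallest library that split still called 1036 bins, which argues against the number of reads alone. Within lineages the share of counts in the top 1% of bins fell with the log2 total count (Pearson r −0.93, exact permutation p = 0.0185, Spearman rho −0.93, p = 0.0278, adjusted p = 0.0185 over 3 relations, 9 libraries, r −0.82 without vinclozolin 1 and DDT 2). A difference in enrichment between libraries that goes with depth may therefore underlie part of this split, as a hypothesis found on the same data. A difference between animals, litters or preparations was not tested and stays open, as does its share in the bins called between DDT and vinclozolin.

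In the 93 bins over 4-fold lower in DDT than in control, on 19 chromosomes, vinclozolin 2 stayed near control while the other vinclozolin libraries did not, with medians over these bins of −0.17 for vinclozolin 2, −1.70 for vinclozolin 1, −1.55 for vinclozolin 3 and −2.19, −2.06 and −1.97 for the DDT libraries (log2 against control). Vinclozolin 2 was the highest vinclozolin library in 88.2% of these bins, against 66.3% of the bins up to 4-fold lower and 33.7% of all tested bins. Since the pattern was first seen in bins of this set, that share restates it, and a difference between single libraries and one between lineages cannot be told apart here. Every window stood at 150 counts or less in 86.0% of them, against 94.7% of the bins up to 4-fold lower and 99.9% of all tested bins. Windows with high counts were thus more frequent here, but most of the set lay far from the window maximum of 300. Saturation would lower the high control counts and so shrink such a deficit, so this share does not test it as a cause. Reads shared between repeated copies were not tested, and the DDT lineage itself, in which all 3 libraries were low, stays an open explanation.

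The uneven spread of DDT-called bins over the chromosomes may come from shifts of whole regions rather than of single bins. With an offset from the surrounding 100 kb, 0 of the 9 chromosome results of DDT against control were kept, and bins higher in DDT turned from under-represented to over-represented on X (odds ratio 0.20 before and 2.35 after). The number of called bins was then 941, of which 587 were among the 1236 called without the offset. A loess offset on the mean abundance of a bin kept 9 of 9, which argues against a bias by abundance. Within lineages the share of counts on chromosome 12 rose and that on X fell with the log2 total count (Pearson r 0.97 and −0.90, exact permutation p = 0.00926 for both, 9 libraries). Shifts of these chromosomes therefore also occurred between libraries of the same lineage. Whether the shift between DDT and control is more than this stays open.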

How the results depend on the processing

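The alternatives with the 100 kb offset, a covariate, thinned counts or windows at 150 or less, and both chromosome tests under an offset, were chosen after seeing the data. Counts are given in the order DDT against control, vinclozolin against control and DDT against vinclozolin, where 1236, 108 and 417 bins were called. Within 1.5 times these counts stayed DESeq2 size factors (1246, 109 and 423), total counts (1241, 106 and 432), bins with every window at 150 or less (1152, 101 and 371) and the 100 kb offset (941, 109 and 503). With DESeq2 size factors 1234, 108 and 416 of the same bins were called, but with the 100 kb offset only 587, 66 and 269. The counts moved to 4364, 376 and 1016 at an adjusted p under 0.1, which admits more bins by construction. They moved to 85, 37 and 32 in 10 kb bins and to 60672, 241 and 1631 in 100 bp windows. With at least 1 count per bin they were 705, 36 and 263, and with at least 100 counts 815, 14 and 745. Fits of the 6 libraries compared gave 1863, 176 and 466, a trended dispersion with the earlier quasi-likelihood fit 509, 22 and 231, and limma-voom 434, 57 and 177. A loess offset on abundance gave 1632, 250 and 771. The log2 total count as covariate gave 7800, 871 and 2454, and the share of counts on chromosome 12 as covariate 827, 1130 and 3014. Thinning to the smallest library, which lowers most counts, gave 751, 66 and 631. With the replicate number as a block the counts were 489, 37 and 148. That number did not pair the libraries, since residuals of libraries with the same number correlated at −0.13 to 0.10 across bins and 2 of 9 libraries correlated best with their own number. Leaving out 1 library gave 217 to 2894, 14 to 477 and 21 to 4213 bins. An arm of 2 libraries was left except where the library belonged to the third lineage, as in the fit with 2894 bins. That fit, without vinclozolin 1, kept all 1236 bins called with 9 libraries. A library of the third lineage is in neither arm and acts mainly through the variance, which is shared over the lineages. For the shifts of the counts in this paragraph the cause was not tested.

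The 26 bins called in both exposed lineages became 43 at an unadjusted p under 1e-05, 52 with fits of the 6 libraries compared, 17 with the replicate number as a block and 4 to 102 with 1 library left out. The 11 chromosome tests that passed became 7 on merged regions, 8 at an unadjusted p under 1e-05 (with chromosome 20 for bins lower in DDT and chromosome 12 for bins higher in vinclozolin, which were not among the 11), 1 with the 100 kb offset and 17 with the loess offset, and the cause was not tested. The difference in the share of counts on X between DDT and control (−0.218) stayed negative without each library in turn (−0.298 to −0.151, exact permutation p 0.1 to 0.3) and without the top 1% of bins (−0.219), but 3 against 3 libraries cannot pass the threshold. No named bin turned its direction under any alternative run at 1 kb. Named bins were selected for libraries of the lineages compared that did not overlap. Leaving out a library could therefore hardly turn a direction, and this is no separate support. All 10 named bins lower in DDT than in control kept their call under each of these in which they were tested, as did 4 of 10 higher in DDT, 6 of 10 lower and 0 of 10 higher in vinclozolin, and 8 of 10 higher and 3 of 10 lower in DDT than in vinclozolin. Of the 10 lower in DDT than in control, the fit with every window at 150 or less tested only 2. These were the bins from 155529001 on chromosome 1 and 130234001 on chromosome 8, as the others held a window over 150. Tests that need sequence or gene positions of the deposited build were not run: promoters, whole genes and gene lists with all their alternatives, and the CpG number, CpG ratio and soft-masked base alternatives. At a median of 45.8 counts per tested bin, simulated changes of 2-fold were recovered in 13.4% of bins for DDT and 0% for vinclozolin. The simulation changed few bins, so these shares set no detection limit for the data.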

Other observations

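In a small set of called bins the mean CPM of a lineage was under 10% of that of the lineage compared. For DDT against control these were 3 bins low in DDT and 1 low in control, and for vinclozolin against control 7 bins low in vinclozolin. The bin from 23667001 on chromosome 2 held 60, 57 and 75 counts in control, 5, 5 and 7 in DDT and 34, 49 and 12 in vinclozolin. The bin from 10323001 on chromosome 12 held 84, 96 and 94 counts in control, 10, 6 and 5 in DDT and 21, 67 and 7 in vinclozolin. The bin from 115810001 on chromosome 2 was low in both exposed lineages, with 2, 9 and 0 counts in DDT and 13, 0 and 4 in vinclozolin, against 50, 85 and 114 in control. The bin from 51058001 on chromosome 6 held 59, 18 and 19 counts in control, 29, 52 and 41 in DDT and 4, 2 and 3 in vinclozolin. These bins were singled out after their values were seen.

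Neighbours of called bins were read only where they were not called themselves, which by itself lowers their fold changes. Adjacent bins had median log2 fold changes of 0.16 and −0.20 for higher and lower bins of DDT and 0.27 and −0.64 for those of vinclozolin. The bins 3 to 50 kb away had median log2 fold changes of 0.12 around bins higher and −0.09 around bins lower in DDT than in control. Around bins called for vinclozolin the medians were 0.07 and −0.07. The share of counts on the mitochondrial genome was 0.0262 ± 0.00705% in DDT, 0.0257 ± 0.00678% in vinclozolin and 0.0247 ± 0.00196% in control (SD, n = 3, exact permutation p = 0.8 and 0.9 against control). Within lineages the log2 total count went with a higher share of counts on chromosome 12 (Pearson r 0.97, exact permutation p = 0.00926, Spearman rho 0.97, adjusted p = 0.0139, 9 libraries, r 0.92 without vinclozolin 1 and DDT 2) and a lower share on X (Pearson r −0.90, exact permutation p = 0.00926, Spearman rho −0.90, r −0.82 without those 2 libraries).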
